A study of Arabidopsis thaliana with 6 samples.

How the data were processed

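Whole rosettes of Arabidopsis thaliana (Col-0, a line expressing a FLAG-tagged ribosomal protein RPL18B) were compared in 3 groups of 2 arrays: control, PBZ and GA. Per the labels, PBZ plants were watered at day 14 with 10 mL of a 50 mg/L solution (0.5 mg per pot), and GA plants were sprayed with 1 mL of 50 µM GA3 every other day; PBZ plants and controls are not described as sprayed. Groups and replicate numbers were taken from the sample titles. The labels' molecule field gives total RNA, while the labels' protocol describes both total RNA and RNA from ribosomes pulled down by the tag, out of the same lysate; which of them was hybridised is not settled beyond the molecule field. RNA was amplified and biotin-labelled, per the labels.

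The deposited table holds linear intensities, 1 value per probe set and array, with 1 decimal. The mean after trimming 2% of values at each end was 100.01 in every array, so the deposited intensities had been scaled to a common mean. The highest intensity was 7413.9 and 38 values were 0. The submitters' processing notes name RMA and the affy package, with no version. RMA gives log2 values, which these are not, and the method that made the table, including its background correction and probe summary, is not given in the sources used here. Because the table was linear, log2(intensity + 10) was taken before testing. The plan had foreseen log2 but no pseudocount, so the pseudocount of 10 was chosen after the table was seen; 26.8% to 29.4% of values per array lay under it. No other normalization was applied.

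The 64 control probe sets were left out, which leaves 22746. The platform annotation given with the data names 1 gene for 13513 of them, several for 503 and none for 8730, which are unnamed here. Symbols were updated through the RefSeq gene table by Entrez number, with 13436 probe sets matched; 1580 have a symbol of their own rather than a locus code alone. No coordinates are given, since the build of the array design is not named.

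Tests used R 4.3.3 and limma 3.58.1. All 6 arrays entered 1 fit with a mean per group (3 residual degrees of freedom), followed by eBayes with its default prior (3.07 prior degrees of freedom) and two-sided moderated tests for PBZ minus control, GA minus control and GA minus PBZ, and an F test over the groups. P-values were adjusted by Benjamini-Hochberg over all 22746 probe sets, and an adjusted p under 0.05 counted as passing. The p-values measure the spread between replicates named biological in the labels, with no further detail on their origin.

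Gene lists were tested with camera (preset inter-gene correlation 0.01) on 1 probe set per gene, the brightest that names 1 gene, and adjusted over the lists within a comparison. Of 43 lists with 666 genes, 113 genes had a probe set of their own by the annotation. Of the lists, 9 had at least 5 measured members and were tested, 23 had 1 to 4 and 11 had 0. Listed genes counted as not measured may lie among the 8730 unnamed probe sets. The measured members therefore need not represent their list. None of the list calls held with an estimated correlation. The list median, mean and camera direction differ in sign for some lists that did not pass, namely GASA in each comparison, chlorophyll in the comparisons with control, and, in GA against control, expansins, flavonoids and the tricarboxylic acid cycle, and sucrose in GA against PBZ. Fry was run as an alternative; it tests whether a list moves on balance one way and does not compare it with other genes.

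The comparisons, lists, tests and naming rule were fixed before the data were examined. In each comparison the rule takes probe sets of 1 gene with its own symbol whose arrays do not overlap between the groups. Of these it names the 10 largest passing changes each way, or the 5 smallest p-values where fewer than 3 pass. It also names up to 4 members of each passing list with the smallest p-values. Last, 25 genes are named whatever their result. They are gibberellin-related genes and RPL18B, and 5 of the 25 have a probe set of their own here. CML37 and GIS in GA against PBZ and LHCB4.3, members of fixed lists too small to test, and BZIP60, JAL22 in GA against PBZ and the genes with a locus code only lie outside the rule and were chosen after their values were seen.

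The pipeline was tested on simulated data in which 100 probe sets were changed in PBZ by 1 and 100 by 2 on the log2 scale. For PBZ against control over 22746 probe sets it called 31% and 90% of them, with 3 false calls; for GA against PBZ it called 26% and 89%, with 3 false calls; and for GA against control it made 0 calls, where 0 was the true number. Alternatives were the replicate number as a block, other variance priors, quantile normalization, median centring, a filter on the 40% dimmest probe sets, leaving out cross-hybridising, multi-gene and unnamed probe sets, leaving out each array, fits of 2 groups, a minimum log2 fold change of 1, other list tests and, added after the table was seen, pseudocounts of 1 and 32, a floor at 10 and a split of the control arrays between PBZ and GA. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.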

Results

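The data were messenger RNA levels in whole rosettes of Arabidopsis thaliana, accession Col-0, measured on 6 Affymetrix-type arrays with 22810 probe sets each. A probe set is a group of short probes read together as 1 value. Of the 3 groups, one was left untreated (control), one was watered with paclobutrazol (PBZ), an inhibitor of gibberellin synthesis, and one was sprayed with the gibberellin GA3 (GA). Each group held 2 arrays from separate biological replicates, per the labels. The plants carried a tagged copy of the ribosomal protein RPL18B, grew in soil under 16 h of light, and were harvested at day 27 by the sample titles and at day 25 by another label of the same samples. The arrays were alike in overall brightness, with median intensities from 32.4 to 33.9. Pearson correlations of log2 values across probe sets were 0.981 to 0.988 within groups and 0.967 to 0.986 between groups. With 2 arrays per group, the number of arrays limits the precision: the median standard error (SE) of a log2 fold change was 0.16. Fold changes below are on the scale of log2(intensity + 10), which understates changes of dim probe sets, and each mean ± SD is of linear intensity with n = 2.

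PBZ against control asked what a block of gibberellin synthesis changed in the rosette. Among genes with a symbol, the largest falls that passed the threshold were in EXPA8 (AT2G40610), an expansin that loosens cell walls, and in BZIP61 (AT3G58120), a bZIP transcription factor. EXPA8 had an intensity of 669 ± 43.3 in control and 73.0 ± 22.5 in PBZ rosettes, 8.32-fold lower (log2 fold change -3.06, SE 0.21, limma adjusted p = 0.00935). BZIP61 went from 63.4 ± 2.97 to 3.55 ± 1.77 (log2 fold change -2.44, SE 0.15, adjusted p = 0.00935). The largest rises that passed among them at this pseudocount were in PDF1.2b (AT2G26020), a plant defensin, and DFR (AT5G42800), an enzyme of anthocyanin synthesis. PDF1.2b rose from 182 ± 63.6 to 1754 ± 65.3, 9.46-fold (log2 fold change 3.24, SE 0.25, adjusted p = 0.0123), on a probe set whose type can also bind related defensins, so which copy changed is uncertain. Its relative PDF1.2A (AT5G44420) had a log2 fold change of 2.67 (SE 0.37) and did not pass over all probe sets (adjusted p = 0.0576).

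The chitinase gene AT2G43570, whose symbol CHI is shared with chalcone isomerase, rose 5.75-fold in PBZ rosettes (log2 fold change 2.52, SE 0.21, adjusted p = 0.0137). Its intensity was also above control in GA (40.2 ± 0.42 in control, 122 ± 8.70 in GA), where it did not pass. OSM34 (AT4G11650), an osmotin-like protein, rose with a log2 fold change of 2.49 (SE 0.29, adjusted p = 0.0405). JRG21 (AT3G55970), a jasmonate-regulated oxygenase, had an intensity of 0.50 in both control arrays and 32.8 ± 0.71 in PBZ (adjusted p = 0.0340). PYK10 (AT3G09260), a beta-glucosidase of endoplasmic reticulum bodies, rose from 111 ± 26.6 to 412 ± 49.5 (log2 fold change 1.81, SE 0.23, adjusted p = 0.0466). ARPN (AT2G02850), a plantacyanin, rose 3.71-fold to 587 ± 19.0 (log2 fold change 1.89, SE 0.16, adjusted p = 0.0160). The plastid gene petN, for a subunit of the cytochrome b6f complex, rose from 3.55 ± 0.78 to 29.4 ± 0.71 (adjusted p = 0.0349). The GA arrays had 17.0 ± 5.52 for petN, also above control without passing. Among the falls, MSRB6 (AT4G04840), a methionine sulfoxide reductase, went from 457 ± 11.7 to 104 ± 0.35 (log2 fold change -2.04, SE 0.11, adjusted p = 0.00909). The thionin THI2.2 (AT5G36910) fell by 1.60 on the log2 scale (adjusted p = 0.0228), the wax ester synthase WSD1 (AT5G37300) fell by 1.38 (adjusted p = 0.0168), the glutathione transferase GSTU27 (AT3G43800) fell by 1.04 (adjusted p = 0.0466), and PRA1.B6 (AT5G07110) fell by 0.99 (adjusted p = 0.0402).

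Of the gene lists, the flavonoid and anthocyanin pathway rose in PBZ rosettes (limma camera, adjusted p = 2.4e-09; adjusted p = 0.0671 with an estimated correlation). Of its 6 measured members 3 rose, and 5 rose when adjusted over the list alone. DFR rose from 15.6 ± 1.56 to 147 ± 5.02, 6.15-fold (log2 fold change 2.62, SE 0.12, adjusted p = 0.00487). UGT75C1 (AT4G14090), an anthocyanin glucosyltransferase, rose 6.02-fold (log2 fold change 2.59, SE 0.20, adjusted p = 0.0119), and UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, 2.39-fold (adjusted p = 0.0482). UF3GT (AT5G54060), which adds xylose to anthocyanins, had a log2 fold change of 2.15 (SE 0.31) and did not pass over all probe sets (adjusted p = 0.0643).

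The expansin list was lower in PBZ rosettes (adjusted p = 0.0459; adjusted p = 0.347 with an estimated correlation), with EXPA8 the 1 member of 11 that fell. Adjusted over the list alone, 4 fell and 1 rose. The 10 measured genes with an EXPA symbol had a median log2 fold change of 0.18. The expansin call ended without control replicate 2 (adjusted p = 0.352), without PBZ replicate 1 (0.234), after quantile normalization (0.0695), after median centring (0.0716), without dim probe sets (0.0635), with fry (0.0846), with a pseudocount of 32 (0.0928) and with a floor of 10 (0.136). Over its 16 alternatives, of which 7 passed, the adjusted p ran from 0.0113 to 0.352. EXLA1 (AT3G45970), EXLA2 (AT4G38400) and EXPB1 (AT2G20750), other expansin-type wall proteins, were 1.99-, 2.29- and 1.83-fold dimmer in PBZ (SE of the log2 fold change 0.20, 0.27 and 0.13) and did not pass over all probe sets (adjusted p = 0.127, 0.153 and 0.0735). The gibberellin perception list was higher (adjusted p = 0.0190; adjusted p = 0.274 with an estimated correlation), with 0 of its 6 members past the threshold over all probe sets, 3 at an unadjusted limma p under 0.05, and 3 higher when adjusted over the list alone. This call ended without control replicate 2 (adjusted p = 0.0854), without PBZ replicate 1 (0.0539) and without dim probe sets (0.0635), within a range of 0.00958 to 0.274 over 16 alternatives. Its gibberellin receptors GID1B (AT3G63010) and GID1A (AT3G05120) were 2.46-fold (SE of the log2 fold change 0.21, adjusted p = 0.0788) and 1.68-fold (SE 0.13, adjusted p = 0.0892) brighter in PBZ. The F-box protein SLY1 (AT4G24210) had a log2 fold change of 0.77 (adjusted p = 0.216), the third receptor GID1C (AT5G27320) one of 0.0241 (adjusted p = 0.977), and SPY (AT3G11540), a negative regulator of the pathway, one of 0.28 (adjusted p = 0.609). The XTH, GASA, chlorophyll, sucrose, tricarboxylic acid cycle and auxin lists did not pass (adjusted p from 0.181 to 0.886).

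In all, 117 of 22746 probe sets passed in PBZ against control, 53 higher and 64 lower (limma with Benjamini-Hochberg adjustment). Of these 54 name 1 gene, 2 name several and 61 are unnamed here. Leaving out any 1 array ended most calls: 0 remained without control replicate 1, control replicate 2, PBZ replicate 1 or PBZ replicate 2, and 4 without GA replicate 1 or GA replicate 2. The count was 4 in a fit of these groups alone, 333 with an intensity trend in the variance prior, 548 without dim probe sets, 23 without cross-hybridising or unnamed probe sets, and 248 or 0 with a pseudocount of 32 or 1. The balance of directions also moved: without cross-hybridising or unnamed probe sets 6 were higher and 17 lower. With a floor of 10 it turned to 58 higher and 41 lower, with 32 of these 99 shared with the 117. Of the genes named above, BZIP61, WSD1, EXLA2, OSM34, JRG21 and petN had a control or PBZ mean under the pseudocount of 10. The size of their fold changes therefore depends on it, and so does their rank among the largest changes. Over 15 or 16 alternatives each, the log2 fold change ran from -3.88 to -1.42 for BZIP61, -2.80 to -0.65 for WSD1 and -1.94 to -0.65 for EXLA2. It ran from 1.63 to 3.34 for OSM34, 0.996 to 4.49 for JRG21 and 0.79 to 2.75 for petN.

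GA against control asked what added gibberellin changed in untreated plants. Among genes with a symbol, the smallest p-values belonged to EXLA1, the calmodulin-like gene CML38 (AT1G76650) and the transcription factor WRKY53 (AT4G23810). Each was brighter in the GA arrays, and none passed the threshold over all probe sets. Unnamed probe sets and genes with a locus code only are left out of this ranking. EXLA1 had 93.0 ± 4.81 in control and 483 ± 137 in GA rosettes (log2 fold change 2.23, SE 0.20, limma adjusted p = 0.109). CML38 had 11.9 ± 6.51 and 112 ± 30.7 (log2 fold change 2.49, SE 0.26, adjusted p = 0.109), and WRKY53 35.6 ± 16.0 and 185 ± 5.66 (log2 fold change 2.14, SE 0.24, adjusted p = 0.109). The ubiquitin ligase PUB23 (AT2G35930) and CML37 (AT5G42380) had log2 fold changes of 1.91 and 1.16 (adjusted p = 0.109 and 0.117). On the lower side the smallest p-values among genes with a symbol belonged to the MADS-box gene AGL72 (AT5G51860), KPL (AT5G63720) and the lectin gene JAL22 (AT2G39310). The plastid protease gene clpP and GIS (AT3G58070), a regulator of trichome formation, came next. In this order the log2 fold changes were -0.68, -0.77, -0.87, -0.66 and -0.75 (adjusted p = 0.197, 0.204, 0.204, 0.233 and 0.241). AGL72 (6.75 ± 1.48 in control, 0.45 ± 0.07 in GA), KPL (8.80 ± 1.84 in control), PUB23 (9.15 ± 4.88 in control) and CML37 (6.55 ± 1.63 in control) had group means under the pseudocount, so the size of their fold changes is set by it. Over 15 alternatives it ran from -2.41 to 0 for AGL72, from -2.30 to -0.00718 for KPL and from 0.61 to 1.90 for CML37, and over 16 from 1.18 to 2.69 for PUB23.

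The xyloglucan endotransglucosylase (XTH) list, enzymes that remodel cell walls, was higher in GA than in control rosettes (camera, adjusted p = 0.00322; adjusted p = 0.310 with an estimated correlation). Of its 8 measured members 0 passed over all probe sets, 4 had an unadjusted limma p under 0.05, and 4 were higher when adjusted over the list alone. XTH18 (AT4G30280), XTH33 (AT1G10550), XTH16 (AT3G23730) and XTH27 (AT2G01850) had log2 fold changes of 1.36, 0.70, 0.57 and 0.47 (SE 0.24, 0.16, 0.14 and 0.14; adjusted p = 0.182, 0.282, 0.301 and 0.391). The control mean of XTH18 (3.1 ± 2.97, against 23.2 ± 1.48 in GA) lay under the pseudocount, and its log2 fold change ran from 0.65 to 2.78 over 15 alternatives. The gibberellin perception list was lower (adjusted p = 0.0424; adjusted p = 0.343 with an estimated correlation), with all 6 log2 fold changes negative, 0 members past the threshold over all probe sets or over the list alone, and 0 at an unadjusted limma p under 0.05. GID1B, GID1A, SNE (AT5G48170) and GID1C had log2 fold changes of -0.49, -0.29, -0.35 and -0.35. That of GID1B, with a GA mean of 6.80 ± 3.39, ran from -0.94 to -0.23 over 15 alternatives. EXPA8 and GASA9 (AT1G22690), a member of a gibberellin-regulated peptide family, had -0.67 and -0.40 (adjusted p = 0.423 and 0.626). The other 7 lists tested did not pass (adjusted p from 0.0813 to 0.999). The XTH call ended without GA replicate 2 (adjusted p = 0.0959) and with fry (0.0671; range 5.9e-04 to 0.310 over 15 alternatives). The perception call ended without control replicate 1, control replicate 2, GA replicate 1 or GA replicate 2 (adjusted p = 0.133, 0.127, 0.180 and 0.0735), without dim probe sets (0.175), with fry (0.0671) and with a pseudocount of 1 (0.0646; range 0.0225 to 0.343 over 16 alternatives).

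In all, 0 of 22746 probe sets passed in GA against control (limma, Benjamini-Hochberg), with 1931 at an unadjusted p under 0.05 where 1137 would be expected by chance and a smallest adjusted p of 0.109. The count of 0 depends on the variance prior and the filter: 193 probe sets passed without dim probe sets, 175 of them higher in GA, and 51 with an intensity trend, 50 of them higher. In both of those fits EXLA1, CML38 and WRKY53 passed (adjusted p = 0.0364, 0.0420 and 0.0420 with the trend; over all alternatives of each gene the adjusted p ran from 0.00412 to 0.695).

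GA against PBZ set a high against a blocked gibberellin supply and used no control array for its means. The expansin-type genes EXLA1 and EXPA8 rose in GA relative to PBZ rosettes. EXLA1 had 41.7 ± 3.39 in PBZ and 483 ± 137 in GA (log2 fold change 3.23, SE 0.20, limma adjusted p = 0.00501), and EXPA8 73.0 ± 22.5 and 417 ± 35.8 (log2 fold change 2.39, SE 0.21, adjusted p = 0.00917). The growth-associated gene EXO (AT4G08950) rose 7.37-fold (log2 fold change 2.88, SE 0.29, adjusted p = 0.0119). RALFL33 (AT4G15800), of the family of peptide signals named rapid alkalinization factors, rose from 329 ± 53.7 to 1297 ± 212 (log2 fold change 1.95, SE 0.20, adjusted p = 0.0128). BZIP61 and MSRB6 rose by 3.40 and 2.18 on the log2 scale (adjusted p = 0.00343 for each).

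The 3 measured members of the touch and wounding list, too few for a list test, all rose in GA relative to PBZ, over all probe sets and adjusted over the list alone. Against control 0 of them passed over all probe sets and 3 were higher when adjusted over the list alone. ZAT10 (AT1G27730), a zinc finger repressor of stress genes, had 42.9 ± 0.14 in PBZ and 406 ± 8.34 in GA (log2 fold change 2.97, SE 0.54, adjusted p = 0.0492), with 101 ± 88.3 in control, where the arrays lay far apart. CML38 rose 4.91-fold (adjusted p = 0.0139) and CML37 rose by 1.59 on the log2 scale (adjusted p = 0.0115). WRKY53 rose by 2.27 (adjusted p = 0.0130). It was the 1 of the 3 measured members of the salicylate and defence list to pass over all probe sets, and 3 were higher when adjusted over the list alone.

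In GA relative to PBZ rosettes, PDF1.2b fell by 3.01 on the log2 scale (adjusted p = 0.00887) and PDF1.2A fell by 2.74 (adjusted p = 0.0230). OSM34 fell by 2.82 (adjusted p = 0.0126) and ARPN fell by 2.51 (adjusted p = 0.00535). PYK10 fell by 2.48 (adjusted p = 0.0114), the endoplasmic reticulum body gene NAI2 (AT3G15950) fell by 1.91 (adjusted p = 0.0136) and the jacalin-related lectin gene JAL33 (AT3G16450) fell by 2.02 (adjusted p = 0.0128). XERICO (AT2G04240), a RING finger protein linked to abscisic acid, had 594 ± 108 in PBZ, 231 ± 18.8 in control and 125 ± 34.0 in GA rosettes (log2 fold change GA against PBZ -2.17, SE 0.22, adjusted p = 0.0119). The trichome regulator GIS fell by 1.13 (adjusted p = 0.0243).

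**Figure D1:**
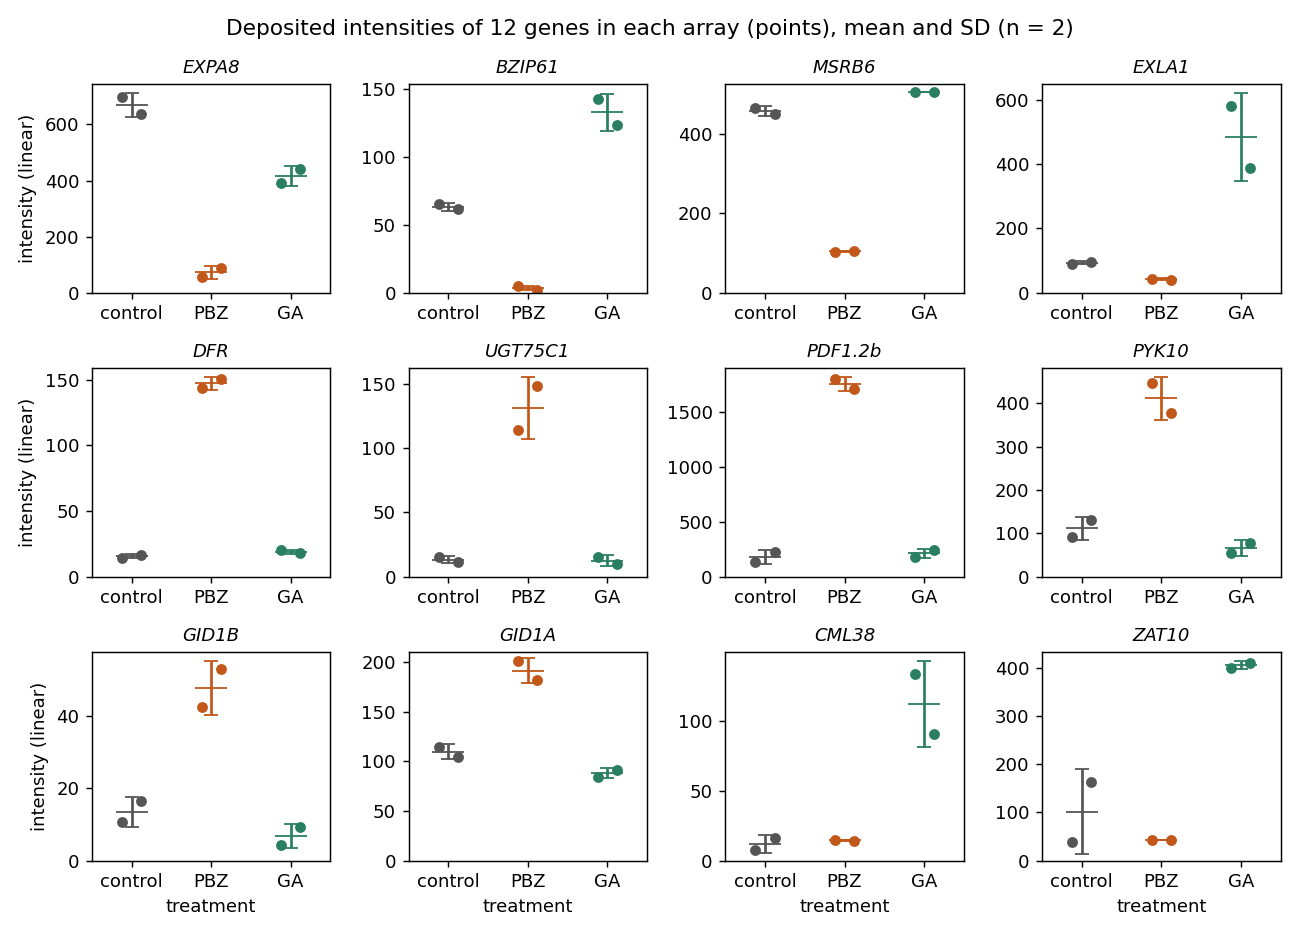
Linear intensity (vertical axis, from 0) of 12 named genes in the control, PBZ and GA arrays; points are arrays, and bars are the mean and SD of n = 2. EXPA8 averaged 73.0 in PBZ against 669 in control and 417 in GA, while DFR averaged 147 in PBZ against 15.6 in control and 18.9 in GA.

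The flavonoid and anthocyanin list was lower in GA than in PBZ rosettes (camera, adjusted p = 2.4e-07; adjusted p = 0.0934 with an estimated correlation), and 5 of 6 members fell, over all probe sets and adjusted over the list alone. UGT75C1, UF3GT, DFR and UGT78D2 were 6.26-, 6.03-, 5.44- and 1.99-fold lower (SE of the log2 fold change 0.20, 0.31, 0.12 and 0.16; adjusted p = 0.00687, 0.0170, 0.00343 and 0.0373). The gibberellin perception list was also lower (adjusted p = 5.3e-04; adjusted p = 0.0934 with an estimated correlation), and 2 of 6 members fell, 3 when adjusted over the list alone. GID1B fell by 1.79 (SE 0.21, adjusted p = 0.0156) and GID1A fell by 1.04 (SE 0.13, adjusted p = 0.0182), while SLY1 and GID1C had -0.97 and -0.38 (adjusted p = 0.0802 and 0.448).

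The XTH list was higher in GA than in PBZ rosettes (adjusted p = 5.3e-04; adjusted p = 0.0934 with an estimated correlation), with 2 of 8 members risen over all probe sets, and 4 risen and 1 fallen when adjusted over the list alone. XTH16 and XTH33 rose by 1.24 and 1.15 (adjusted p = 0.0139 and 0.0244), while XTH18 and XTH32 (AT2G36870) had log2 fold changes of 1.15 and -0.85 and did not pass (adjusted p = 0.0657 and 0.0631). The expansin list was higher too (adjusted p = 0.0187; adjusted p = 0.268 with an estimated correlation), with 4 of 11 members risen over all probe sets, and 6 risen and 3 fallen when adjusted over the list alone. Its call ended without PBZ replicate 1 (adjusted p = 0.0889), without dim probe sets (0.0602) and with a floor of 10 (0.0631), within a range of 0.0104 to 0.268 over 16 alternatives. Besides EXLA1 and EXPA8, EXLA2 and EXPB1 rose by 1.96 and 1.01 (adjusted p = 0.0234 and 0.0218). Among the 10 measured genes with an EXPA symbol, EXPA8 alone passed, and the median log2 fold change was -0.22. GASA9 had a log2 fold change of -0.16 (adjusted p = 0.694). The other 5 lists tested did not pass (adjusted p from 0.0820 to 0.961). Of these the auxin list, with all 7 log2 fold changes negative, passed with fry alone (fry adjusted p = 0.00912). The 7 lists of primary metabolism with measured members (light harvesting, Calvin-Benson cycle, chlorophyll, starch synthesis, starch degradation, sucrose and tricarboxylic acid cycle) held 35 of them. Of these 0 passed in GA against PBZ, with 5 at an unadjusted limma p under 0.05, and 0 passed in either comparison with control, with 2 such members for PBZ and 1 for GA. Over all 22746 probe sets 675 passed in GA against PBZ and 117 in PBZ against control. Few of 35 members would thus be expected to pass, and the absence of calls does not show that these pathways were unchanged. Adjusted over each list alone, the antenna gene LHCB4.3 (AT2G40100) was higher in PBZ than in control and lower in GA than in PBZ (log2 fold changes 0.49 and -0.62). This grouping of lists was made after their values were seen.

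**Figure D2:**
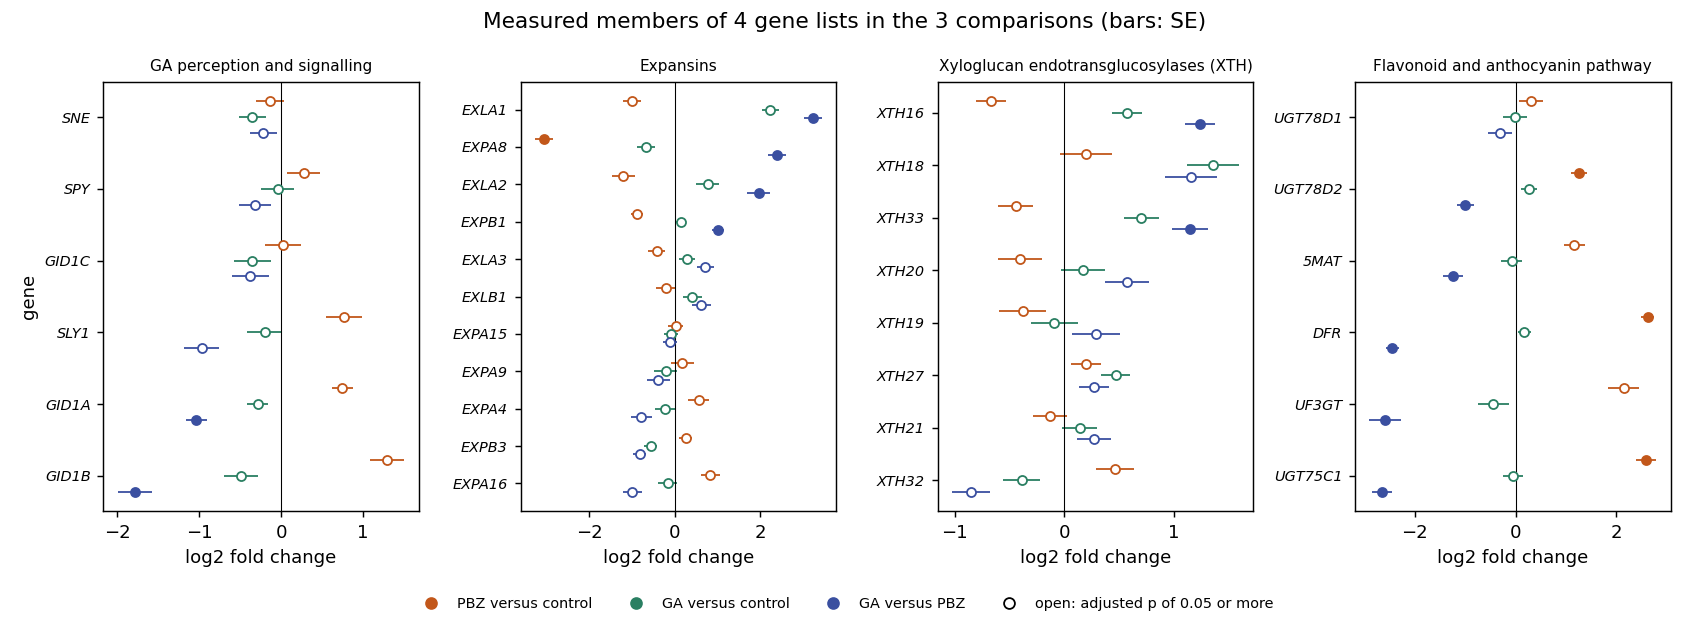
Log2 fold change (horizontal axis) of each measured member of 4 gene lists in the 3 comparisons, with bars for the SE; filled points have an adjusted p under 0.05 over all probe sets. DFR lies at 2.62 in PBZ versus control and at -2.44 in GA versus PBZ, and no member is filled in GA versus control.

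In all, 675 probe sets passed in GA against PBZ, 445 higher and 230 lower (limma, Benjamini-Hochberg). Of these 325 name 1 gene, 8 name several and 342 are unnamed here. The count was 0 without GA replicate 1 or GA replicate 2, 37 without PBZ replicate 1, 24 without PBZ replicate 2, and 284 without either control array, which equals a fit of these groups alone. It was 1349 without dim probe sets, 1040 with an intensity trend, 243 without cross-hybridising or unnamed probe sets, 94 with a pseudocount of 1 and 292 with a floor of 10. Of the genes named above, BZIP61, EXLA2, CML37, XTH18, XTH33, OSM34, UF3GT and GID1B had a PBZ or GA mean under the pseudocount. Over 15 or 16 alternatives each, the log2 fold change ran from 2.21 to 4.93 for BZIP61, 1.19 to 2.87 for EXLA2, 0.78 to 3.16 for CML37, 0.57 to 2.15 for XTH18 and 0.65 to 1.71 for XTH33. It ran from -4.23 to -1.77 for OSM34, -3.56 to -1.70 for UF3GT and -2.70 to -1.04 for GID1B. The 3'/5' signal ratio of GAPDH control probe sets, a sign of RNA quality, was 2.06 ± 0.73 in PBZ, 2.68 ± 0.04 in control and 3.03 ± 0.46 in GA arrays. That of actin was 12.1 ± 0.86, 12.3 ± 3.44 and 15.5 ± 4.60, and that of ubiquitin was 2.08 ± 0.19, 2.22 ± 0.17 and 2.12 ± 0.02. The array holds other control probe sets for these transcripts, whose ends lay closer together. For GAPDH their mean 3' and 5' intensities were 1301 and 1347 in PBZ, 1217 and 1411 in control, and 1336 and 1340 in GA. For actin they were 2049 and 520, 2070 and 494, and 2021 and 458. For ubiquitin they were 2688 and 2372, 2901 and 2222, and 2653 and 2081. A test for any difference among the 3 groups (limma F test) called 382 probe sets, with 3639 at an unadjusted p under 0.05. It called 0 without any 1 of the PBZ or GA arrays, 19 without control replicate 1 and 48 without control replicate 2.

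The design also asked whether PBZ and GA moved the same genes in opposite directions. EXPA8 had log2 fold changes against control of -3.06 for PBZ and -0.67 for GA, the latter not passing, whereas BZIP61, EXLA1 and EXLA2 had log2 fold changes below 0 for PBZ and above 0 for GA (BZIP61 passed for PBZ, and 0 of them passed for GA). Of the 117 probe sets called in PBZ against control, 69 (59.0%) had a GA fold change of the other sign. The share was 32.6% (range 31.2% to 34.7% over 20 simulations) where simulated GA arrays had no effect. A GA response unrelated to that of PBZ was not simulated and would also raise this share. The simulated noise was independent between probe sets, so the simulated range may be too narrow. Of the 675 probe sets called between GA and PBZ, the control mean lay between the treated means in 579 (85.8%, against 42.1% of all probe sets; choosing probe sets by their gap between GA and PBZ raises this share). Control lay nearer to GA than to PBZ in 435 of them. Across all probe sets, which are not independent replicates, the PBZ and GA fold changes had a Pearson r of 0.161 and a Spearman rho of 0.230. Unchanged groups sharing the control arrays, simulated 100 times, gave an r of 0.499 (0.487 to 0.516) and a rho of 0.473. Responses in unrelated directions would also lower r below the simulated value, so a lower r alone does not show opposite shifts. The covariance was 0.0150 against a simulated 0.0189 (0.0180 to 0.0197), a difference of -0.00389. With 1 control array for PBZ and the other for GA, so that none was shared, the r was -0.0456 with control replicate 1 for PBZ and -0.111 with control replicate 2 for PBZ (covariance -0.00504 and -0.0136). This split was chosen after the data were seen. The r was 0.402 without control replicate 2, 0.0289 without dim probe sets and 0.315 with a pseudocount of 1.

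**Figure D3:**
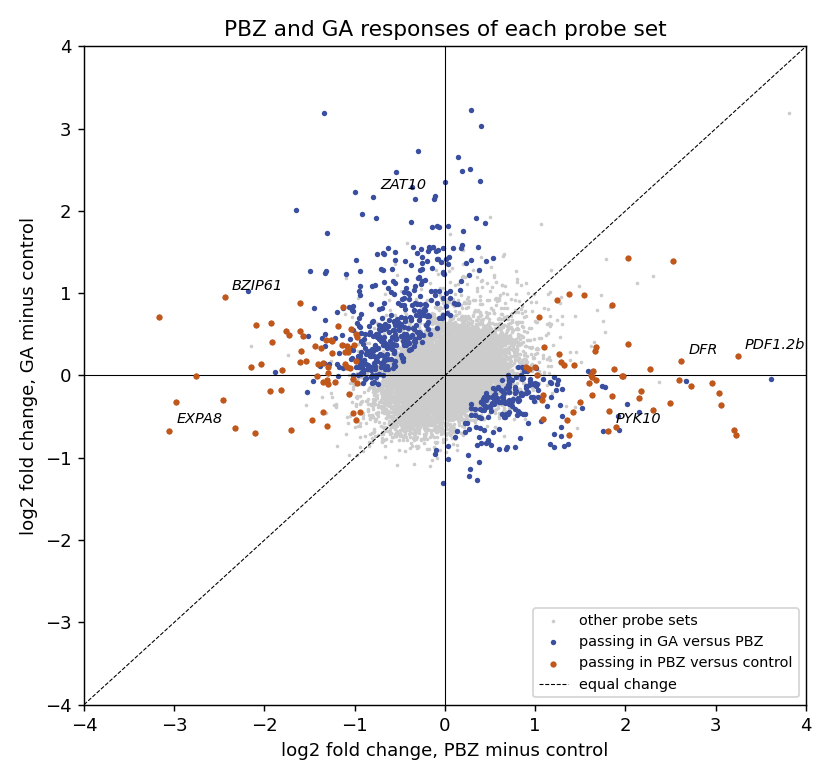
Log2 fold change of each of the 22746 probe sets for PBZ minus control (horizontal axis) against GA minus control (vertical axis); blue points passed in GA versus PBZ, orange points in PBZ versus control, and the dashed line marks equal change. The orange points lie far from 0 along the PBZ axis, and 69 of the 117 have opposite signs on the axes.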

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

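The pseudocounts, the floor and the split of the control arrays were chosen after seeing the data. All 56 named changes that passed kept their sign under every alternative run, and the 9 list calls kept their direction. For most alternatives the sign of a named change could not turn, since the arrays of the compared groups did not overlap in any passing change. Leaving out an array, or another prior, block or pseudocount, leaves such a sign as it is. Counts of passing probe sets moved widely, in the order PBZ against control, GA against control, GA against PBZ, and any difference (main 117, 0, 675 and 382). With the replicate number as a block they were 47, 1, 391 and 83. Deviations of same-numbered arrays correlated at 0.0147, 0.0313 and -7.7e-04, which shows no strong shared shift across all probe sets. A batch that moves few genes cannot be excluded this way. With an intensity trend the counts were 333, 51, 1040 and 746. Without dim probe sets they were 548, 193, 1349 and 1133. Without cross-hybridising, multi-gene and unnamed probe sets, 23 passed for PBZ against control, 243 for GA against PBZ and 99 for any difference. In fits of 2 groups, 4 and 284 passed for PBZ against control and GA against PBZ. A pseudocount of 1 gave 0, 0, 94 and 0, and one of 32 gave 248 for PBZ against control and 628 for any difference. A floor at 10 gave 4 for GA against control, 292 for GA against PBZ (54.1% higher, main 65.9%) and 124 for any difference. With 1 array left out, a lone array is assumed to vary like the other groups and 1 residual degree of freedom is lost: PBZ against control ranged from 0 to 4, GA against control stayed at 0, GA against PBZ ranged from 0 to 284 and any difference from 0 to 48. Of the 56 named changes, 3 to 27 still passed with 1 array left out, and 14 named changes that had not passed did so under some alternative. The cause of the other shifts was not tested, except that filters change how many probe sets are tested.

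List counts (main 3, 2 and 4) were 0, 0 and 0 with an estimated correlation and 1, 0 and 2 without dim probe sets. With fry they were 2, 0 and 5, and GA against control had 1 with a pseudocount of 1. Without dim probe sets the XTH list had too few members for a test. With 1 array left out they ranged from 1 to 3 for PBZ against control, 0 to 2 for GA against control and 3 to 4 for GA against PBZ. The correlation of PBZ and GA responses (main 0.161) was 0.0289 without dim probe sets and 0.315 with a pseudocount of 1, and ranged from 0.128 to 0.402 with 1 array left out. It turned to -0.0456 and -0.111 in the 2 splits of the control arrays, where no array is shared. GID1C in PBZ against control, which did not pass, changed sign after quantile normalization (-0.0177) and median centring (-0.0109) and ranged from -0.20 to 0.25 with 1 array left out (main 0.0241), and GASA9 in GA against PBZ ranged from -0.36 to 0.0372 (main -0.16); the cause was not tested. Signal over background limits dim genes, since 26.8% to 29.4% of values per array lie under the pseudocount.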

Other observations

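The tests of the jasmonate genes (in both versions), of the touch genes without each array, of the spread between control arrays and of shifts in opposite directions (with and without a shared control array), and the gene families, were chosen after results bearing on them had been seen. Among 29 families formed by a shared symbol stem or by plastid encoding (at least 8 measured genes), the RALFL peptides were lower in PBZ than in control rosettes (camera, adjusted p = 0.0361; adjusted p = 0.577 with an estimated correlation) and higher in GA than in PBZ (adjusted p = 0.00252; adjusted p = 0.474 with an estimated correlation), where RALFL33 alone of 10 members passed. The BZIP transcription factors were higher in GA than in control (adjusted p = 0.0178; adjusted p = 0.718 with an estimated correlation) and than in PBZ (adjusted p = 0.00726; adjusted p = 0.474 with an estimated correlation). In the latter 2 of 14 passed, BZIP61 and BZIP60, a regulator of the unfolded protein response, whose intensity was 461 ± 22.3 in GA, 256 ± 12.9 in PBZ and 253 ± 19.5 in control (SD, n = 2; limma adjusted p = 0.0321 for GA against PBZ). The XTH family, whose members largely overlap the fixed list, was higher in GA than in control (adjusted p = 0.00839; adjusted p = 0.718 with an estimated correlation) and than in PBZ (adjusted p = 0.0109; adjusted p = 0.474 with an estimated correlation), with 0 and 2 of 10 members past the threshold. The PUB ubiquitin ligases were higher in GA than in control (adjusted p = 0.0319; adjusted p = 0.718 with an estimated correlation), with 0 of 9 past it. The TET and PRA families were lower in PBZ than in control (adjusted p = 0.0348 and 0.0361; adjusted p = 0.577 for each with an estimated correlation), with 0 of 15 and 1 of 11 members past it. These directions were the same after quantile normalization and median centring. The family tests were not rerun with another pseudocount, a floor or a dim filter. TET16 (7.9 in control, 1.2 in PBZ) and TET9 (8.9 and 2.3) lay under the pseudocount, while TET3 (295 and 228) lay above it. The EXPA expansins, 10 measured genes, did not pass (camera, adjusted p = 0.711 in GA against PBZ and 0.746 in PBZ against control). Their median log2 fold changes were -0.22 and 0.18, against the direction of the expansin list.

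Some of the largest changes lay in genes with a locus code only, named here after their values were seen. AT3G44970, a cytochrome P450, had 314 ± 43.7 in PBZ, 24.7 ± 2.62 in control and 11.1 ± 4.38 in GA rosettes (limma adjusted p = 0.00909 for PBZ against control). AT1G66100, of the thionin family, had 93.2 ± 30.3 in PBZ, 901 ± 130 in control and 1475 ± 50.9 in GA (adjusted p = 0.0105 for PBZ against control and 0.00456 for GA against PBZ).

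PYK10, NAI2, JAL22 and JAL33 were higher in PBZ than in GA rosettes, with log2 fold changes for GA against PBZ of -2.48, -1.91, -1.65 and -2.02 (limma adjusted p from 0.0114 to 0.0136). PYK10 is abundant in roots, so root tissue in the PBZ samples is a candidate explanation; the 11 measured genes of a root marker list of 35 had a median PBZ-minus-GA log2 fold change of 0.23 (bootstrap interval -0.0471 to 0.42). Only 4 of them exceeded an intensity of 20 in any group, and the brightest went both ways (PER21 208 in PBZ against 138 in GA, AT1G12080 39.2 against 93.4), so root tissue cannot be told apart from a change within the rosette. A wider rise of jasmonate-inducible genes may also be behind it, but the 3 measured members of the fixed jasmonate list (JMT, THI2.1 and PDF1.2A) had a median PBZ-minus-GA log2 fold change of 0.94, between the bounds of 0.5 and 1 set for the test, and so decide nothing. The test was first run with JRG21 and PDF1.2b added, which gave a median of 1.64, over the upper bound; both were then left out because they had been picked for their rise in PBZ.

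CML37, CML38 and ZAT10, genes induced by touch and wounding, were higher in GA than in PBZ rosettes, and GA plants alone are described as sprayed. As the mean of the 3 genes on the log2 scale, GA exceeded control by 1.94 and PBZ by 2.29, and the excess over 50% of the latter gap was 0.80 (SE 0.32). This excess passed the bound of 2 SE set beforehand for spraying of the GA plants, a candidate explanation. The SE pools the 3 groups, though most of the spread lay between the control arrays. Their means were 4.56 and 5.44, against 4.69 and 4.61 in PBZ and 6.99 and 6.89 in GA. The SE therefore understates the spread of control. A response to GA3 could pass the same bound, so the pass does not favour spraying. Without control replicate 1 or control replicate 2 it was 0.36 or 1.24 (4.77 or 16.6 times its SE, with the lone control array adding no spread of its own), and without any 1 of the PBZ or GA arrays it was 0.77 to 0.82, 1.86 to 1.98 times its SE and so below the bound. The labels describe no group as sprayed without GA3, so a response to GA3 itself stays open; a response to both a lower and a higher supply would place PBZ below control, and that difference was -0.35 (SE 0.36), which decides nothing.

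More probe sets passed between GA and PBZ than in either comparison with control. A larger spread between the control arrays was a candidate technical source. The median absolute log2 difference of the control pair was 0.865 times that of the PBZ pair (0.168 against 0.194, and 0.150 for the GA pair). The variance is pooled over all 6 arrays and enters each comparison alike, with a median SE of 0.163 in each. A wider control pair would thus raise the SE of every comparison, and not of those with control alone. The pair differences therefore cannot test this source, and no conclusion is drawn from them. Shifts in opposite directions from control could give the pattern, though shifts in unrelated directions could too and were not tested. The covariance of the PBZ and GA fold changes was 0.0150, below the 0.0180 to 0.0197 of simulated unchanged groups sharing the control arrays. Of the probe sets called for PBZ, 59.0% had a GA change of the other sign, against a simulated 31.2% to 34.7% with no GA effect. An unrelated GA response would also raise this share, so the share cannot tell it from opposite shifts. With a different control array for each treatment the covariance averaged -0.00933. It was below 0 in all 18 combinations of control and treated arrays, which are not independent. The r in the splits with the treated means was -0.0456 and -0.111, close to 0. The values thus leave shifts in opposite directions as a hypothesis.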
